A study of Mus musculus with 4 samples.

How the data were processed

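Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on microdissected kidneys of wild-type mouse embryos at embryonic day 18.5. WT1 is a zinc-finger transcription factor of the developing kidney, named for Wilms' tumour. Per the labels, 2 samples were precipitated with a WT1 antibody and 2 with IgG as a negative control, from 2 experiments described as independent. Per the labels' protocols, the recovered DNA was cut with AluI and MseI or with HaeIII and MseI before adapters were ligated, and libraries went through 18 rounds of PCR. Which enzyme pair was used for which sample is not given in the sources used here.

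The deposited files used here are a peak list for each WT1 sample and a table of regions found in both. Per the submitters' processing notes the genome build is mm10. The aligner, the peak caller, their versions and whether IgG reads entered the peak calling are not given in the sources used here. Each deposited peak list gives a position and 1 value per peak, which runs from 0 to 0.0499 in both lists and is read here as a p-value or q-value cut at 0.05; which of the pair it is, is not given in the sources used here. It is called the significance value below, and it is the authors' own value for each peak. The deposited table of both replicates carries a value between 5.19e-08 and 0.555 per region. Its product with the rank grew by between 8.07e-08 and 1 at every step and no step was smaller than the one before, which is how a global irreproducible discovery rate (IDR) runs. It is read here as that q-value-like error rate. All 17234 of its regions overlapped a peak of both replicates and began and ended at a peak edge of 1 of the lists. The part common to overlapping peaks would also meet these conditions. The widest region, at 1814 bp, exceeds the widest peak of replicates 1 and 2 (1615 and 1611 bp), so at least that region spans its overlapping peaks. The files hold no read counts, peak heights or fold enrichments, so the depth behind a peak is unknown, and the IgG samples were not analysed here. With peaks as the unit, intervals cover counting error over peaks or genes only.

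Regions with an IDR of 0.05 or lower are called reproducible peaks. Peaks of the replicates were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). The second list was placed at random on the same chromosomes 200 times for comparison. Gene positions came from a table of RefSeq genes of GRCm38.p6, the assembly that mm10 is based on. The table gives no strand, exons or transcription start sites, and no genome sequence was used. The distances to transcription start sites planned before the data were examined were therefore replaced by distances to the nearer end of the gene, which does not tell 5' from 3' ends. The planned motif and 8-mer comparisons and the background matched on promoter CpG content were not run. Random positions were planned on sequence without gaps. Instead, random positions and random placements were drawn between the outermost peaks of each chromosome. They can fall in gaps, where no peak can be called, so ratios to the random level may be too high. Positions are 1-based, and a peak was placed by its midpoint.

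The share of reproducible peaks within 1 kb of an end of any of 21887 protein-coding genes, and inside genes, was set against 1000 sets of random positions matched on chromosome (two-sided permutation p, smallest possible value 0.002). For 20 gene lists fixed before the data were examined, genes with at least 1 reproducible peak within 10 kb of an end were counted and compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 20 lists. Of 552 symbols on 19 lists, 550 matched the table; the olfactory receptor list was taken by symbol. Shares have exact Clopper-Pearson 95% intervals. For each list the share was also computed from the 4411 peaks with the smallest significance values of each replicate alone. Genes are named by a rule fixed before the data were examined: 20 genes listed in advance, the gene with the nearest end to each of the 10 regions with the lowest IDR, and up to 4 members of each list, those with the lowest-IDR peak within 10 kb. Results for some of these genes are not reported here.

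Alternatives were stricter and looser IDR thresholds, other overlap rules, other windows, peaks away from gene ends, each replicate alone, and, added after the data were seen, random moves of 10 to 100 kb, whole genes with 10 kb around them, lists matched on gene length and neighbouring genes, rotation of the peak calls along the gene order, lists without the genes of the podocyte and nephron progenitor lists, regions without the widest ones, and the correlation of replicates among reproducible regions only. Matched lists and rotations were drawn 10000 times each and give observed over expected counts. The functions were tested on simulated data: for the overlap of the replicates, all 18064 of the simulated shared peaks among 53132 were recovered, with 190 others counted as shared because they met a neighbour, and for the gene lists, a podocyte list with peaks planted at 40% of its members was called in 100 of 100 simulations over 21887 genes, with 0 calls in 1900 tests of lists without planted peaks. The simulated peaks of the list test lay near independently drawn gene ends, and the simulated shared peaks overlapped by construction. These simulations therefore check the functions and do not measure error rates for clustered peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.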

Results

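WT1 occupancy was mapped by ChIP-seq in microdissected mouse kidneys late in embryonic life, a stage at which nephron progenitors and forming glomeruli are present side by side. There were 2 WT1 samples and 2 IgG control samples. Values for the WT1 samples are peak lists, and the IgG samples were not analysed here. WT1 replicate 1 held 53132 peaks with a median width of 134 bp (interquartile range 111 to 186), covering 8.45 Mb. WT1 replicate 2 held 57641 peaks with a median width of 150 bp (117 to 210), covering 10.4 Mb. With n = 2 samples of 1 group there is no test between samples, and statements about genes rest on the set of peaks found in both.

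The first question was how far the replicates found the same sites. Most sites with the strongest significance recurred, and most of the weaker ones did not. Of the peaks in replicate 1, 18116 (34.1%, 95% interval 33.7 to 34.5) overlapped a peak of replicate 2, and of those in replicate 2, 17730 (30.8%, 30.4 to 31.1) overlapped a peak of replicate 1. Random placement gave 0.799% and 0.738% on average, so sharing was 42.7 and 41.7 times the random level. Against peaks moved by 10 to 100 kb, which keeps their regional density, it was 29.3 and 28.5 times. When each list was ordered by significance value and split into 10 equal parts, in the first part 90.8% of replicate 1 and 92.6% of replicate 2 were shared. In the fifth part the shares were 28.5% and 19.5%. Over the 17234 regions of the overlap table, the significance values of the replicates had a Spearman rho of 0.60, a description across peaks, which are not independent replicates.

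**Figure D1:**
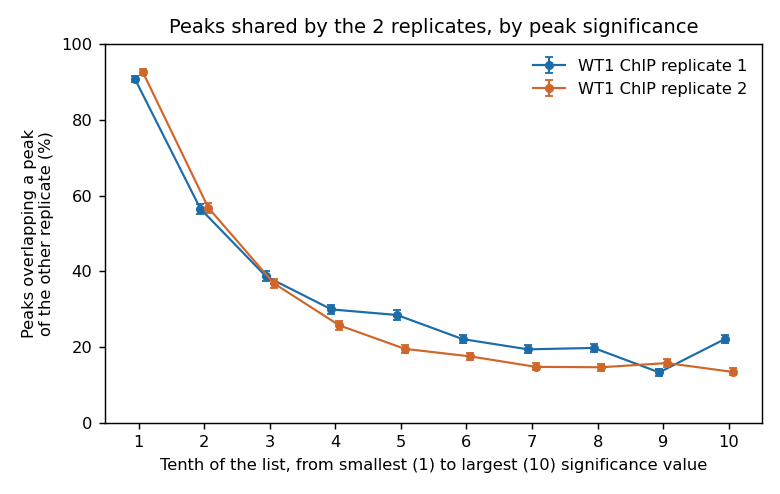
Share of peaks of each WT1 replicate that overlap a peak of the other (y axis, percent) against 10 equal parts of the list by significance value (x axis, 1 holding the smallest values). Points are shares and bars exact 95% intervals; sharing is 90.8% and 92.6% in the first part and 22.1% and 13.4% in the last, and in replicate 1 the ninth part, at 13.3%, is lower than the last.

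Peaks present in a single replicate differed from shared ones in significance and place. The median significance value was 0.00938 for shared and 0.0267 for unshared peaks of replicate 1, and 0.00122 and 0.0161 for those of replicate 2. In replicate 1, 14.9% of shared peaks (95% interval 14.4 to 15.4) and 3.86% of unshared peaks (3.66 to 4.07) lay within 1 kb of a protein-coding gene end. In replicate 2 these shares were 14.6% (14.1 to 15.2) and 10.9% (10.6 to 11.2). Where peaks of the replicates overlapped one to one (16021 pairs), 40.2% had the identical start base and 39.9% the identical end base, so edge positions are not independent between the replicates.

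At an IDR of 0.05 or lower, 4411 regions remained, 25.6% of the overlap table, with a median width of 372 bp. None lay on an unplaced contig or the Y chromosome, and 51 lay on the X chromosome. Thresholds of 0.01 and 0.1 gave 2940 and 5547 regions.

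The next question was where in the genome these reproducible peaks lay. They gathered at gene ends: 19.7% (95% interval 18.49 to 20.9) lay within 1 kb of an end of a protein-coding gene, against 3.21% of random positions, a ratio of 6.13 (permutation p = 0.002, the smallest 1000 sets can give). Within 100 bp the share was 3.70% against 0.367%. Most peaks were nevertheless away from gene ends, with a median distance of 16.3 kb, and 42.4% of them had a gene end within 10 kb. Inside genes lay 53.4% of the peaks against 41.4% of random positions (permutation p = 0.002). Moved by 10 to 100 kb at random, the same peaks lay inside genes in 53.2% of cases (permutation p = 0.8) and within 1 kb of a gene end in 4.69% (permutation p = 0.002), so the excess inside genes was not seen against nearby positions while the excess at gene ends was. These shares inside genes include peaks near gene ends. Inside genes but more than 1 kb from any gene end lay 43.5% of the peaks. That was above the 39.6% of random positions and below the 50.5% after the moves (permutation p = 0.002 for each).

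**Figure D2:**
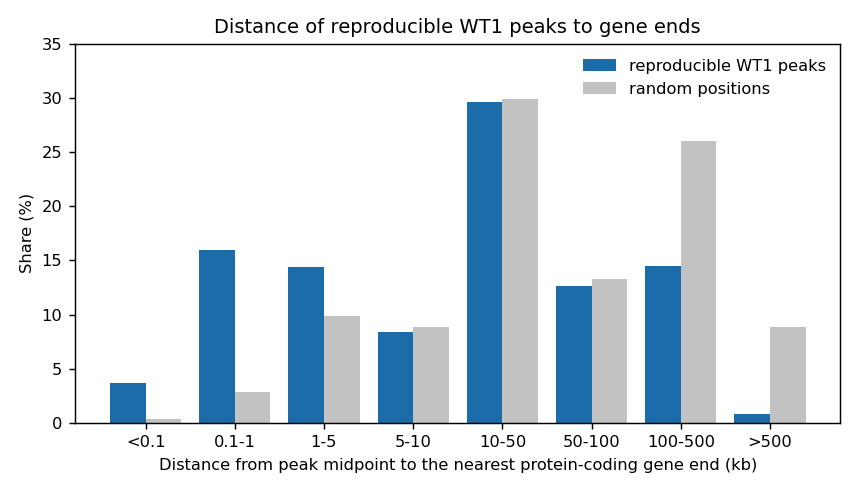
Distance from the midpoint of each of the 4411 reproducible peaks to the nearest protein-coding gene end (x axis, kb, unequal bins) as a share of all peaks (y axis, percent, blue), beside random positions on the same chromosomes (grey). Peaks exceed random positions below 5 kb and fall short of them beyond 100 kb.

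The 10 regions with the lowest IDR were mostly far from gene ends. The first lay 26.8 kb outside Aak1, a kinase of clathrin-mediated endocytosis (chromosome 6, 86822152 to 86822770, IDR 5.19e-08). The second lay inside Ksr2, a scaffold of the Raf-MEK-ERK cascade, 80.1 kb from its nearer end, and the seventh inside Mical3. Of the others, the one next to Pard6b, a cell polarity gene, was 8.06 kb outside it. Those next to Inpp5f, Slamf9, Atp5mpl, Skap1, Trib2 and Ncam1 were 19.5, 21.7, 22.5, 42.8, 92.7 and 123 kb from the named gene. Pard6b also had a second reproducible peak inside the gene, and Ksr2 had 5 inside it.

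The main comparison asked which groups of genes carried reproducible peaks. Of the 21887 protein-coding genes, 2226 (10.2%) had at least 1 within 10 kb of an end. Podocyte genes, nephron progenitor genes and genes of the Notch and FGF pathways did so in 37.1% to 43.3% of cases. Ureteric bud, BMP and TGF-beta, Hippo and retinoic acid genes were also above the other genes, and olfactory receptor genes were far below. In all, 8 of the 20 lists lay above and 1 below at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg adjusted). Some genes stand on several lists, so the results of the lists are not independent.

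**Figure D3:**
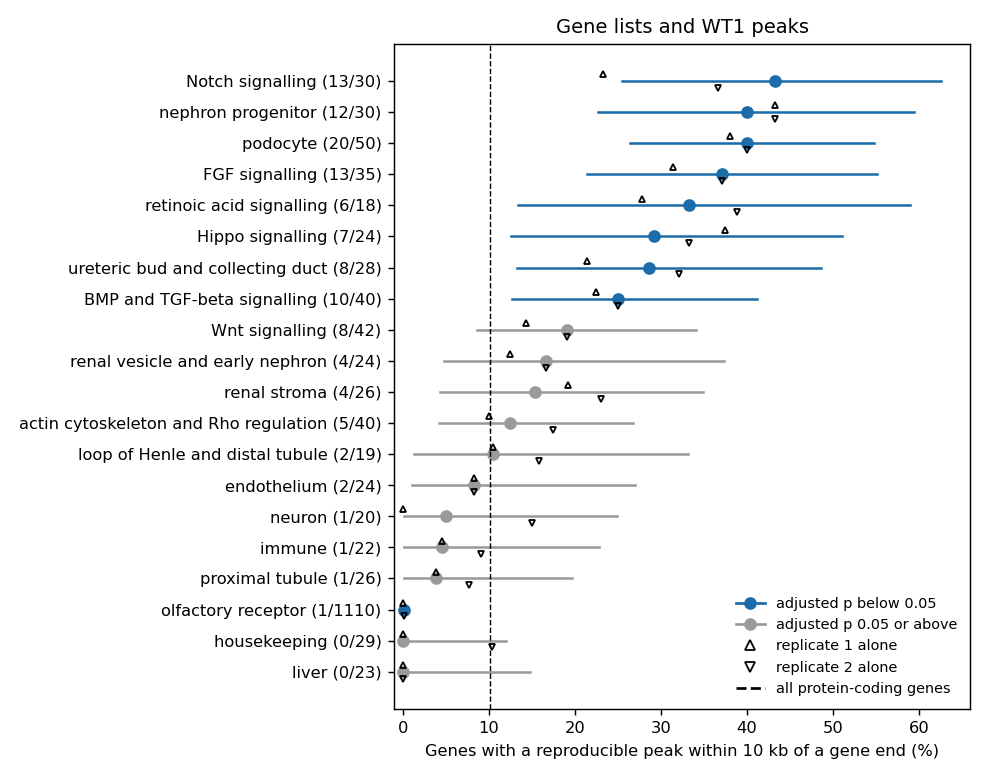
Share of the genes of each list with a reproducible peak within 10 kb of a gene end (x axis, percent; counts beside the names). Circles and lines are shares and exact 95% intervals, blue for an adjusted p under 0.05; triangles are shares from the top peaks of each replicate alone, and the dashed line is the 10.2% of all protein-coding genes.

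Podocytes are the epithelial cells of the glomerular filter. Of 50 podocyte genes, 20 had a reproducible peak (40.0%, 95% interval 26.4 to 54.8) against 10.1% of other genes, an odds ratio of 5.93 (3.36 to 10.5) and an adjusted p of 2.99e-07 (Fisher's exact test). From the top peaks of replicates 1 and 2 alone the shares were 38.0% and 40.0%. The lowest-IDR peaks belonged to Sema3g, a secreted semaphorin (chromosome 14, 31226622 to 31227720, inside the gene, IDR 1.43e-07), Bmp7, Nes, which encodes the intermediate filament nestin, and Sulf1, a heparan sulfate sulfatase. Sulf1 had 4 such peaks, 1 of them 68 bp from a gene end. Wt1 itself had a peak 95 bp from its lower-coordinate end (chromosome 2, 105126176 to 105126691, IDR 4.99e-06), with significance values of 5.2e-14 and 1.39e-35 in replicates 1 and 2.

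Several podocyte genes had their peaks inside the gene or not at all under this rule. Nphs1, which encodes nephrin of the slit diaphragm (chromosome 7, 30458207 to 30488623), held a reproducible peak at 30478056 to 30478820 (IDR 5.23e-07), 10.2 kb from the nearer end and so just outside the window. Synpo, which encodes the actin-associated protein synaptopodin, held 2 inside the gene, the nearer 12.4 kb from an end. At Podxl, which encodes podocalyxin, the only overlap region within 10 kb had an IDR of 0.312, and at Col4a3, a collagen chain of the glomerular basement membrane, 0.188, so neither passed.

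**Figure D4:**
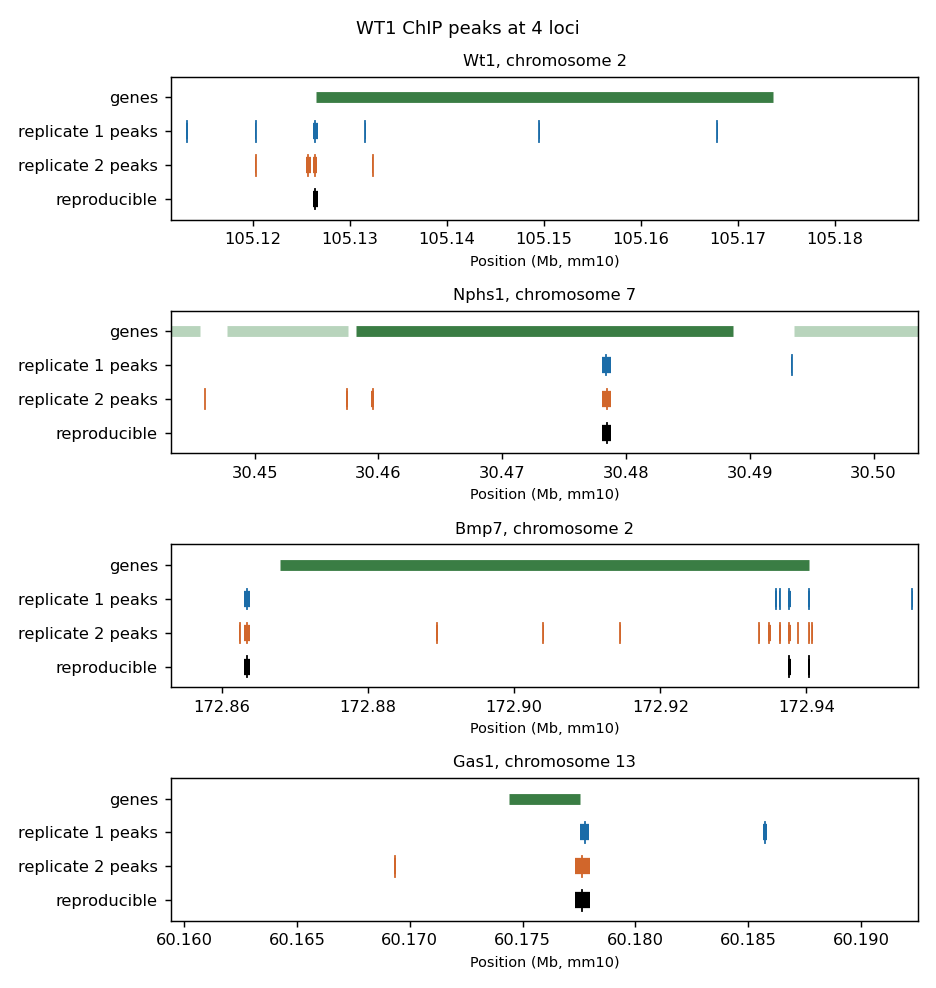
Peaks at Wt1, Nphs1, Bmp7 and Gas1 on mm10 (x axes, Mb), with the named gene in dark green and neighbouring protein-coding genes in light green, peaks of replicate 1 in blue, of replicate 2 in orange and reproducible peaks in black; thin lines mark midpoints. Each locus holds at least 1 reproducible peak, inside the gene at Nphs1 and at a gene end at Wt1, Bmp7 and Gas1.

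Nephron progenitors are the mesenchymal cells that give rise to the nephron epithelium. Of 30 such genes, 12 had a reproducible peak (40.0%, 22.7 to 59.4), an odds ratio of 5.91 (2.85 to 12.3) and an adjusted p of 8.24e-05 (Fisher's exact test). The call was lost with a 1 kb window (4 of 30, odds ratio 3.58, adjusted p = 0.0847, Fisher's exact test), and over the alternatives the adjusted p was 4.64e-06 at the lowest. Rspo1, a Wnt agonist, had 2, the stronger at IDR 6.89e-07. Uncx, a homeobox gene, had 2, the nearer 207 bp from an end. Gas1, which encodes a membrane-anchored protein, had a peak 112 bp from an end (chromosome 13, 60177301 to 60177992, IDR 3.13e-06). Hoxd10 and Hoxd11 were counted through the same peak (chromosome 2, 74681490 to 74681803). Pax2, a transcription factor of nephron formation, had 2 inside the gene, at IDR 0.0139 and 0.018, and Osr1 had 1, 3.55 kb from an end, at IDR 0.0447. At Six2, which maintains progenitor renewal, no overlap region lay within 10 kb. It had 0 peaks of replicate 1 and 4 of replicate 2 there, and its nearest reproducible peak was 49.4 kb away (chromosome 17, 85737320 to 85737905, IDR 6e-07). Cited1 on the X chromosome had no peak in either replicate, and Sall1 and Wnt4 had overlap regions only above the threshold, the lowest at IDR 0.186 and 0.109.

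For fibroblast growth factor signalling, 13 of 35 genes had a reproducible peak (37.1%, 21.5 to 55.1; odds ratio 5.24, 2.64 to 10.4; adjusted p = 8.24e-05, Fisher's exact test). They included the ligand genes Fgf20 (199 bp from an end, chromosome 8, 40286835 to 40287469, IDR 1.25e-05), Fgf16 (455 bp, IDR 0.00584) and Fgf8 (2.55 kb, IDR 0.00269, also within 10 kb of Npm3 and Oga). Of all 22 genes with an Fgf symbol only these 3 had a peak (13.6%, odds ratio 1.395, 0.413 to 4.72; adjusted p = 0.601 over 39 families chosen after the results were seen, Fisher's exact test). The receptor gene Fgfr4 had 1 at 651 bp and Flrt2 had 2 inside the gene. Gas1 belongs to this list too. Without the genes that the podocyte and progenitor lists also hold, 11 of 31 remained, with an odds ratio of 4.88 and an adjusted p of 5.77e-04 (Fisher's exact test). With peaks more than 1 kb from any gene end the call was lost (5 of 35, odds ratio 3.10, adjusted p = 0.0800, Fisher's exact test), and the lowest adjusted p over the alternatives was 5.56e-05.

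For bone morphogenetic protein and TGF-beta signalling, 10 of 40 genes had a reproducible peak (25%, 12.7 to 41.2; odds ratio 2.95, 1.44 to 6.05; adjusted p = 0.0162, Fisher's exact test). Bmp7, a ligand required for progenitor survival, had 3, the strongest 4.55 kb outside its lower-coordinate end (chromosome 2, 172863031 to 172863893, IDR 3.43e-07). Smad3, a signal transducer, had 1 at 446 bp from an end and 3 more inside the gene, Smad4 had 1 at 4.8 kb, and the receptor gene Tgfbr2 had 1 at 253 bp. Bmper, which encodes a BMP-binding protein, had none within 10 kb of an end but held 1 inside the gene, 45.8 kb from an end (IDR 0.00806). The call was lost at an IDR of 0.01 (odds ratio 2.78, adjusted p = 0.0529), with a 1 kb window (3.32 and 0.0771) and with peaks more than 1 kb from any gene end (2.66 and 0.115), by Fisher's exact test; the lowest adjusted p over the alternatives was 8.00e-04.

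Notch signalling, which patterns the nephron, had 13 of 30 genes with a reproducible peak (43.3%, 25.5 to 62.6; odds ratio 6.79, 3.29 to 14.0; adjusted p = 1.81e-05, Fisher's exact test). Heyl, a transcriptional effector, had 3 reproducible peaks, the strongest at IDR 8.29e-07. Hes1, another effector, had 4, the ligand gene Dll1 2, and the coactivator gene Maml3 had 11 inside the gene, 2 of them within 10 kb of an end. Replicates 1 and 2 alone gave 23.3% and 36.7% for this list. At an IDR of 0.01, 7 of 30 had a peak (odds ratio 4.00, adjusted p = 0.0143, Fisher's exact test). Over all alternatives the odds ratio, or the ratio to expected counts, ran from 3.08 to 9.81, and the call was kept.

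Hippo signalling had 7 of 24 genes with a reproducible peak (29.2%, odds ratio 3.65, 1.51 to 8.80; adjusted p = 0.0181, Fisher's exact test), among them Wwc1, Dchs1, Lats2 and Tead3. The peak at Dchs1 lay within 10 kb of an end of Ilk, Taf10 and Tpp1 as well, and that at Tead3 of Tulp1. Retinoic acid signalling had 6 of 18 (33.3%, odds ratio 4.43, 1.66 to 11.8; adjusted p = 0.0174, Fisher's exact test), with Rxra at 119 bp from an end (IDR 3.69e-07), Rara, Rarg and Stra6. Against random lists matched on gene length and neighbouring genes the adjusted p became 0.108 for Hippo and 0.0605 for retinoic acid signalling (random lists), so neither call held there. The shares were 2.31 and 2.93 times the matched expectation, against 2.87 and 3.28 times the share of other genes without matching. For Hippo the call was also lost with peaks more than 1 kb from any gene end (2 of 24, odds ratio 1.69, adjusted p = 0.583, Fisher's exact test), the lowest adjusted p over the alternatives being 8.48e-05. For retinoic acid signalling it was lost with a 50 kb window (odds ratio 1.89, adjusted p = 0.278), a 1 kb window (2.90 and 0.376) and an IDR of 0.01 (3.75 and 0.0772), by Fisher's exact test, the lowest being 0.00477.

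Among the other kidney cell types, ureteric bud and collecting duct genes were above other genes with 8 of 28 (28.6%, 13.2 to 48.7; odds ratio 3.54, 1.56 to 8.05; adjusted p = 0.0162, Fisher's exact test). Its lowest-IDR members were Wnt11, Dusp6, Hoxb7 and Elf5. Dusp6 is also a feedback inhibitor of FGF signalling, and the peak at Hoxb7 was within 10 kb of Hoxb8 and Hoxb9 too. Dusp6 and Etv4 were also counted on the FGF list, and Wnt11 and Wnt7b on the Wnt list. No alternative removed these genes, so the result is not separate from those of the signalling lists. The call was lost with a 50 kb window (odds ratio 1.93, adjusted p = 0.247) and with peaks more than 1 kb from any gene end (2.23 and 0.310), where the odds ratio was lower, and from replicate 1 alone (2.75 and 0.0796) and with a 1 kb window (3.88 and 0.0771), by Fisher's exact test; the lowest adjusted p was 0.00477. The remaining lists of nephron and stroma cells did not pass. Renal vesicle genes had 4 of 24, among them Pax8 with 4 reproducible peaks, adjusted p = 0.46 (Fisher's exact test). Renal stroma had 4 of 26, among them Ren1, Foxd1 and Lamc3, adjusted p = 0.472 (Fisher's exact test). Proximal tubule genes had 1 of 26 (Spp2), adjusted p = 0.682, and loop of Henle and distal tubule genes 2 of 19, among them Wnk4, adjusted p = 1 (all by Fisher's exact test). The intervals of the odds ratio, 0.604 to 5.18, 0.553 to 4.67, 0.0478 to 2.61 and 0.24 to 4.50 in that order, all include 1.

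Endothelial, immune, neuronal, liver, housekeeping and olfactory receptor genes had shares below that of all genes, and of these lists only the olfactory receptors passed the test. Endothelial genes had 2 of 24 (Plvap and Cldn5), immune genes 1 of 22 (Cd68) and neuronal genes 1 of 20 (Rbfox3). The direction turned for neuronal genes from replicate 2 alone (3 of 20, odds ratio 1.501, 0.44 to 5.13) and for endothelial genes with a 50 kb window (9 of 24, odds ratio 1.79, 0.781 to 4.08), at an IDR of 0.01 (odds ratio 1.19) and with a 1 kb window (1.01). The peaks at Plvap, Cldn5 and Cd68 each lay within 10 kb of another gene. Liver genes had 0 of 23, with an exact 95% interval up to 14.8%, and Alb had none, with 1 peak of each replicate within 10 kb but no overlap region. Housekeeping genes had 0 of 29, with an exact 95% interval up to 11.9%, adjusted p = 0.126 (Fisher's exact test). With all overlapped peaks 9 of them had a peak (31.03%), an odds ratio of 1.201 (0.547 to 2.64), which turns the direction. At Gapdh, replicate 1 had 1 peak within 10 kb and replicate 2 had 0. From replicate 2 alone 10.3% of housekeeping genes had a peak, and from replicate 1 alone 0%. Actin cytoskeleton genes had 5 of 40, including Wasl, Actn1, Nck2 and Inf2, adjusted p = 0.747, and Wnt signalling genes had 8 of 42, including Rspo1, Axin2, Wnt11 and Ctnnb1, adjusted p = 0.126 (Fisher's exact test). Both passed with all overlapped peaks, actin with 19 of 40 (odds ratio 2.42 against 1.26, adjusted p = 0.0170) and Wnt with 22 of 42 (2.94 against 2.08, adjusted p = 0.00199), by Fisher's exact test. Counting peaks anywhere in the gene or within 10 kb, actin had 12 (odds ratio 2.73, adjusted p = 0.0208) and Wnt 11 (2.26 and 0.0476), by Fisher's exact test, and over the alternatives the highest adjusted p was 1 and 0.989. Of 1110 olfactory receptor genes only Olfr1323 had a peak, a share of 0.0901% against 10.7% of other genes (adjusted p = 3.68e-50, Fisher's exact test). These genes stand in large arrays, and rotation of the peak calls along the gene order, which keeps neighbours together, also left this list below the others.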

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

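The overlap table held 9 regions on unplaced contigs, sequences not assigned to a chromosome, which enter the counts of the overlap table and the correlation over it but no comparison of genes or locations. They are listed because they lie outside those comparisons; no control list was used, so whether they exceed background is not known. Replicates 1 and 2 had 19 and 20 peaks on such contigs. The lowest IDR among the 9 regions was 0.181, so none was reproducible at 0.05.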

How the results depend on the processing

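No paired analysis was possible because only the WT1 samples had peak lists, so no groups were compared. The planned motif and 8-mer comparisons and the CpG-matched lists were not run, since they need genome sequence. Moves of 10 to 100 kb, matched lists, rotations, whole genes, trimmed lists, the removal of the widest regions and the correlation among reproducible regions were chosen after seeing the data. The shared percent of replicates 1 and 2 was 27.7 and 25.5 with a reciprocal overlap of 50%, 30.5 and 28.1 with midpoints within 100 bp, and 40.2 and 36.3 for the stronger 50% of each list. The reproducible set held 2940 regions at an IDR of 0.01 and 17234 without a threshold, and the Spearman rho of significance values was 0.72 among reproducible regions. The excess of peaks within 1 kb of gene ends kept its direction and a permutation p of 0.002 under all alternatives run, from 14.5% for all overlapped peaks to 21.1% for replicate 2 alone. Within 5 kb the share was 34.0%. The share inside genes was 53.4%, against 53.2% after moves of 10 to 100 kb, and so not in excess there. The number of lists above other genes, 8 of 20, became 4 with a 1 kb window and 4 with peaks more than 1 kb from any gene end; it was 7 to 8 from each replicate alone, 11 with all overlapped peaks and 6 with matched lists. By Fisher's exact test or random lists, the podocyte, Notch and olfactory receptor lists passed under all 10 alternatives that could change them, the nephron progenitor list under 9 of 10 (adjusted p = 0.0847 with a 1 kb window) and the FGF list under 10 of 11 (0.08 with peaks more than 1 kb from gene ends). BMP and TGF-beta passed under 8 of 11, Hippo under 8 of 10, and the ureteric bud and retinoic acid lists under 6 of 10 each. Wnt signalling (2 alternatives), actin cytoskeleton (2) and renal vesicle (1) passed only with all overlapped peaks or whole genes. Of 205 values of single lists under alternatives, 185 stayed on their side of the threshold, 15 lost it and 5 gained it; the cause was not tested. Small lists limit what can be seen, and read depth is unknown.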

Other observations

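Gene families were defined by symbol and tested after the results of the lists were seen, and some of their members, such as Hoxd11, Foxc1, Smad3 and Heyl, also stand on those lists. Of 39 families tested, 7 lay above other genes and 1 below (Fisher's exact test, adjusted p under 0.05), and 6 and 1 also passed when the peak calls were rotated along the gene order. Hox genes, which set position along the body axis, had a peak within 10 kb for 22 of 39 members (56.4%; odds ratio 11.53, 6.12 to 21.8), served by 14 distinct peaks. Sox transcription factors had 11 of 19 (57.9%), served by 15 distinct peaks. Fox factors had 12 of 44 and semaphorins and plexins, guidance ligands and receptors, 10 of 29 (adjusted p = 0.00628 and 0.00245, Fisher's exact test). Smad and Tgf genes had 8 of 19. Id, Hes and Hey genes had 5 of 13, with an adjusted p of 0.0338 by Fisher's exact test and 0.0819 by rotation. The 21 protocadherin genes with a peak share a single distinct peak, since these gene models share an end, so that family's count is 1 site. Vomeronasal receptors had 0 of 355.

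Reproducible peaks also gathered in clusters. The densest 100 kb windows held 12 peaks each: at Hes1 on chromosome 16 (30008609 to 30103182) and at Cxxc5 on chromosome 18 (35829287 to 35927839). Windows at Zbtb7c and Ahdc1 held 9 each, and the one at Midn and Sbno2 held 8. The highest count in 200 random placements was 6. These placements were uniform along each chromosome and do not keep the gathering of peaks near genes, so they cannot tell clusters from uneven regional density. Maml3 and Msi2, an RNA-binding protein gene, carried 11 and 10 peaks within the gene and 10 kb around it. Their lengths are 418 and 379 kb, while Midn, of 12.4 kb, carried 7.

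The tests in the next 3 paragraphs were chosen after the results they bear on were seen, except the test of edge digits and, for podocyte genes, that of transcription factors of other tissues. No biological explanation from the design was tested, since a single group has peak lists.

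The first pattern is that overlapping peaks of the replicates share edges to the base. The exact start was shared by 6446 and the exact end by 6397 of 16021 pairs, while a difference of 1 bp was seen in 76 and 73. A difference of 2 bp was more frequent, with 95 and 89 starts and 91 and 87 ends in the 2 directions. Peaks of exactly 36 bp were 52.0 and 50.6 times as frequent in replicates 1 and 2 as those of neighbouring widths on average. For 72 bp the values were 6.89 and 9.61, and the cause of these excesses was not tested. A coordinate grid is argued against, since no last digit held more than 10.3% of edges. The same data deposited as both samples are argued against, since at most 34.1% of a list was found in the other. That share cannot tell whether a library was sequenced more than once, since weak peaks could then fall under the threshold. Identical edges were 74.2 times as frequent as any distance of 1 to 20 bp on average, at the less enriched edge, which any source of fixed ends would give. Restriction digestion before ligation is a possible explanation and stays open, since enzyme sites at the edges were not looked up.

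The second pattern is a low number of peaks on the X chromosome: 0.299 reproducible regions per Mb against 1.77 on autosomes, a ratio of 0.169 (95% interval 0.125 to 0.222), and 1.26 on the lowest autosome. The ratio was 0.181 at an IDR of 0.001, and 0.296 and 0.200 in the peak lists of replicates 1 and 2. Gene number does not account for it, since 28 of 960 X genes outside the olfactory receptors had a peak within 10 kb against 2197 of 19561 autosomal genes, an odds ratio of 0.237 (0.163 to 0.347). A lower copy number of X in a pool with male embryos may contribute, but the ratio of 0.169 lies below what copy number alone gives in proportion, and how far fewer copies push weak sites under a peak threshold cannot be told apart without read counts. Mappability of X sequence stays open and was not tested.

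The third pattern is the excess of podocyte, progenitor and signalling genes with a peak. Peaks at all active promoters are argued against, in the main setting and for podocyte genes, by the housekeeping genes. Their share of reproducible peaks has an upper bound of 11.9%, below the lower bound of 26.4% for podocyte genes. By the odds ratio, housekeeping genes (up to 2.45) lay below podocyte, Notch, nephron progenitor and FGF genes. They overlapped BMP and TGF-beta (from 1.44), Hippo (1.51), retinoic acid (1.66) and Wnt genes (0.963), where the comparison cannot decide. With all overlapped peaks the housekeeping odds ratio was 1.201 (0.547 to 2.64) against a podocyte lower bound of 3.42. From replicate 2 alone the intervals of the odds ratio overlapped (housekeeping up to 3.244, podocyte from 3.237). They also overlapped with a 1 kb window (6.42 and 4.37) and at an IDR of 0.01 (3.62 and 3.08). The same held with peaks more than 1 kb from any gene end (5.14 and 2.69). By the odds ratio the argument therefore cannot be made in these settings, of which the 1 kb window lies closest to gene ends. Except from replicate 2 alone (3 of 29), housekeeping genes had 0 of 29 with a peak in them, which leaves a wide interval. Exact intervals of the shares, as used in the main setting, were not computed there. Ribosomal protein genes had 12 of 89 (adjusted p = 0.436, Fisher's exact test). Peaks near developmental regulators of any tissue were set against 50 neural, heart and muscle transcription factors. Of these 4 had a peak, an odds ratio of 0.768 (0.276 to 2.13). That interval lies below that of podocyte genes (from 3.36), the only comparison fixed in advance, which argues against the explanation for podocyte genes. It also lies below those of Notch (3.29), nephron progenitor (2.85) and FGF genes (2.64), but cannot decide for them. The 50 factors belong to particular tissues, while Notch and FGF genes are pathway members. Among the progenitor genes with a peak are Hoxc11, Hoxd10 and Hoxd11. The interval of the 50 factors overlaps those of BMP and TGF-beta (from 1.44), Hippo (1.51), retinoic acid (1.66) and Wnt genes (0.963), where it cannot decide either. The Sox, Hox and Fox families, with odds ratios of 12.2, 11.53 and 3.32, go the other way, so peaks near regulators of those families stay open. Gene length and neighbouring genes as the whole cause are argued against by the 260 genes of the podocyte, nephron progenitor and all 6 signalling lists, whatever the call of each, of which 84 had a peak, 3.01 times the number expected from matched genes (95% interval 2.49 to 3.58) and 3.26 times without matching, although the Hippo and retinoic acid lists alone lost their calls against matched lists (adjusted p = 0.108 and 0.0605, permutation over random lists). Accessible chromatin and promoter base composition were not tested and stay open.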
